A study of Homo sapiens with 9 samples.

How the data were processed

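Total RNA was depleted of ribosomal RNA, made into directional libraries with UMI adaptors and sequenced in paired reads of 100 bases on a NovaSeq instrument, per the labels' protocols. Per the submitters' processing notes, reads were aligned to hg38 with STAR 2.5.2a, genes and repeat subfamilies were counted together with TEtoolkit, and DESeq and DESeq2 1.22.2 were used for normalisation and testing. The strand setting, the annotation release and whether the UMIs were used are not given in the sources used here.

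Per the file headers the deposited tables hold raw counts per gene or repeat subfamily, and a normalized signal (normalized counts) which the authors made by dividing the raw counts by 1 DESeq size factor per library. The deposited baseMean is the mean of these normalized counts in each row. The deposited log2FoldChange is KO over WT with its standard error. The deposited Wald statistic is a score that the authors' DESeq2 made as the log2 difference over its standard error, and pvalue and padj are deposited as plain p-values. A further deposited column holds log10 of p with its negative sign left on. The deposited counts had already been filtered, with a smallest row total of 37, and held 21003 genes and 1111 repeat subfamilies.

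Counts of genes and repeats were kept in 1 table. edgeR filterByExpr by genotype with a minimum count of 10 kept 17777 genes and 1052 repeats. Of the genes before this filter, 5201 carried only an Ensembl identifier. TMM scaling and the edgeR quasi-likelihood F test with a single genotype term gave KO against WT, and a fit with 4 groups gave the contrasts between clones. P-values were adjusted by Benjamini-Hochberg over all genes and repeats of a contrast, and a call needed adjusted p below 0.05. CPM are counts per 1e6 after TMM scaling, values after ± are SD, and SE is the standard error of the edgeR log2 difference. SE here covers the spread between libraries as modelled by edgeR. Positions came from GENCODE release 44, in which 20689 genes were found. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, matplotlib 3.10.9, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

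Before the data were examined, 43 lists of genes and repeats were written down, along with the alternatives to the test and the rule for naming genes. The 41 lists with at least 5 tested members were compared with all other genes by camera on voom values, with the preset correlation of 0.01 between members, and again with the correlation estimated from the libraries. They were also tested with fry, which asks whether a list differs from no change and not from other genes. Named genes were MATR3, its neighbour SNHG4 and a short set of innate genes, the 10 largest rises and 10 largest falls with mean CPM of at least 1 and no overlap between KO and WT libraries, up to 4 members with the smallest p of each list, 5 repeats each way, and 3 genes each way per contrast of clones. Where a gene had 0 counts in all KO libraries, its fold is a lower bound from a floor of 3 counts pooled over the 4 KO libraries, and such bounds cover counting error only. Gene families, genes silent in 1 genotype and the scan along chromosomes were added after the data had been examined.

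The test was tried on simulated data, in which 100 genes were changed at each fold in a table of 18829. Tested on simulated data it recovered 79% of 2-fold and 44% of 1.5-fold changes between KO and WT, with 12 of 135 calls false (8.89%). For KO clone 1 against WT these were 78% and 49% with 5.22% false, and for KO clone 5 against KO clone 1 they were 72% and 35% with 7.76% false. The simulated libraries were drawn independently, without differences between clones, and few genes were changed. These rates therefore need not hold for the real calls. The chromosome scan, tested on simulated data of 11738 genes, called 7 of 7 doubled windows and 0 of 279 others.

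Libraries with the same replicate number deviated from their clones in the same direction, with correlations of 0.128 to 0.599 in all 12 comparisons. Because the deviations mirror each other in a clone with 2 libraries, these are not independent. A fit with replicate number as a block was therefore run as an alternative.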

Results

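The series compares HAP1 cells, a near-haploid line derived from a chronic myeloid leukaemia, with and without MATR3, which encodes the nuclear RNA- and DNA-binding protein matrin 3. Its title concerns activation of cGAS-STING, the cytosolic DNA sensor and its adaptor. Total RNA was sequenced from 9 libraries: wild-type (WT) clone 1 (n = 3), WT clone 7 (n = 2), knockout (KO) clone 1 (n = 2) and KO clone 5 (n = 2). Per the labels the clones were bought from a supplier, with WT controls from different batches. Nothing says that replicates of a clone came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Library totals ran from 16.1 to 34.4 in units of 1e6 counts. Correlations of log-CPM across genes were 0.982 to 0.995 within a clone, 0.973 to 0.991 between clones of a genotype and 0.943 to 0.967 between genotypes. The first principal component held 60.3% of the variance and separated KO from WT. WT clone 1 replicate 1 stood apart from the other WT libraries on the second (13.5%), and its repeat share was 14.0% against 7.90 to 10.5% in the others.

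MATR3 RNA was 4.92-fold lower in KO cells, at 219 ± 5.8 CPM in WT (n = 5) and 44.4 ± 3.6 CPM in KO (n = 4) libraries (log2 difference -2.30, SE 0.06, edgeR adjusted p = 2.0e-09). Each WT library held 211 to 224 CPM and each KO library 40.8 to 49.3 CPM. KO clone 1 was lower by 2.36 log2 units (SE 0.08) and KO clone 5 by 2.25 (SE 0.08). A second annotated entry that overlaps MATR3 gave -2.14, but reads in the overlap cannot be assigned between them. SNHG4, a small nucleolar RNA host gene at the same locus, was at 70.5 ± 7.7 CPM in WT and 63.3 ± 4.1 CPM in KO libraries (-0.16, SE 0.08, edgeR adjusted p = 0.21).

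Among genes with the largest rises in KO cells, FAT3, a giant atypical cadherin, rose from 0.259 ± 0.18 to 22.9 ± 13 CPM (log2 6.37, SE 0.50) and NEFL, the neurofilament light chain, from 0.769 ± 0.26 to 29.6 ± 14 CPM (5.24, SE 0.37). ATCAY, which encodes the neuronal protein caytaxin, went from 0.172 ± 0.05 to 6.05 ± 0.69 CPM (5.05, SE 0.20). The adhesion molecule VCAM1 rose by 4.31 (SE 0.21) to 15.1 ± 1.1 CPM, the actin-binding protein gene POF1B by 4.08 (SE 0.20) to 38.9 ± 4.8 CPM, and tropomyosin 2 (TPM2) by 3.85 (SE 0.12), from 9.19 ± 1.5 to 133 ± 15 CPM. CALHM5, a member of the calcium homeostasis modulator family, rose by 3.59 (SE 0.33), FAM19A5, which encodes a secreted brain protein, by 3.43 (SE 0.29), and NPTX2, a neuronal pentraxin, by 3.37 (SE 0.20). The long non-coding RNA HOTAIR rose by 3.58 (SE 0.19, 0.592 to 7.37 CPM), with the caveat that it lies antisense to HOXC11 and the strand setting of the counting is unknown. Adjusted p-values of these 10 genes (edgeR) ran from 4.1e-09 for TPM2 to 9.1e-06 for CALHM5. They were chosen among genes whose KO and WT libraries did not overlap.

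The deepest falls ended in 0 counts in all 4 KO libraries, so their folds are lower bounds that cover counting error only. COL11A1, a fibrillar collagen gene, was at least 190.1-fold lower (6.17 ± 1.94 CPM in WT, edgeR adjusted p = 6.6e-06), FUT9, a fucosyltransferase, at least 121-fold (4.0 ± 1.14 CPM, edgeR adjusted p = 5.7e-06). VEGFC, a lymphatic growth factor, was at least 104-fold lower (3.53 ± 0.622 CPM, edgeR adjusted p = 1.5e-06) and CNTNAP5, a neuronal adhesion gene, at least 77.6-fold (2.83 ± 2.60 CPM, edgeR adjusted p = 0.0021). The others were the zinc finger genes ZNF676 (at least 182-fold, 6.91 ± 8.75 CPM in WT), ZNF43 (149.9-fold, 5.73 ± 7.27 CPM) and ZNF729 (94.9-fold, 3.51 ± 4.30 CPM), the non-coding RNA LINC02582 (144-fold, 5.16 ± 4.70 CPM), the meiosis gene MEIOB (109-fold, 4.20 ± 5.32 CPM) and KIAA1210 (85.1-fold, 3.14 ± 3.44 CPM). These 6, like CNTNAP5, had an SD between WT libraries near or above their mean. The edgeR adjusted p-values of these 6, at 0.0051 to 0.014, became 0.0594 to 0.110 with robust dispersion estimates. Without WT clone 1 replicate 1 the bounds were 104-fold for ZNF676, 85.5-fold for ZNF43, 61.4-fold for MEIOB, 57.5-fold for ZNF729 and 55.4-fold for KIAA1210. The last 4 of these genes then no longer passed the low-count filter and were not tested, and this also held without WT clone 1 replicate 2 or 3 or WT clone 7 replicate 1, and for MEIOB and ZNF43 without WT clone 7 replicate 2.

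Of 17777 tested genes, 4123 changed between KO and WT, 2014 of them higher and 2109 lower, and 1084 changed at least 2-fold (477 higher, 607 lower). The median gene did not move (0.00). KO and WT libraries did not overlap at 4154 genes (23.4%), of which 3575 were among those called. Chance gives 1.59% if all libraries are taken as independent. Libraries of a clone are alike, so the chance share is higher for genes that differ between clones. With the libraries of each clone summed, 1639 genes were called. Leaving out KO clone 1 gave 2338 and leaving out KO clone 5 gave 2614. In the table the authors deposited, 4455 genes have an adjusted p below 0.05 (2066 higher, 2389 lower), 3936 of them also called here, and its log2 differences correlated with those of edgeR at 0.999.

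Interferon-stimulated genes rose as a group, with 15 of 34 tested members higher and 1 lower (17 and 2 adjusted over the list alone, median 0.25, camera adjusted p = 0.00087, and 0.284 with an estimated correlation between members). IFITM1 and IFITM2, which block viral entry, rose from 2.05 ± 0.49 to 14.2 ± 3.4 CPM (2.79, SE 0.19, edgeR adjusted p = 1.2e-06) and from 1.04 ± 0.13 to 7.36 ± 2.0 CPM (2.81, SE 0.20). ISG15, a ubiquitin-like modifier, rose from 5.21 ± 0.94 to 16.9 ± 1.8 CPM (1.69, SE 0.13), and OAS2, which makes 2',5'-linked oligoadenylates, from 2.14 ± 0.43 to 7.70 ± 1.8 CPM (1.84, SE 0.19). Chosen after their values were seen, the antiviral GTPase gene MX1 rose by 3.17 (SE 0.32, 0.146 to 1.31 CPM) and IFI27, the member that fell, dropped by 1.39 (SE 0.17). IFIT1, an RNA-binding effector, was at 3.63 ± 0.59 CPM in WT and 2.60 ± 0.96 CPM in KO libraries (-0.48, SE 0.23, edgeR adjusted p = 0.17), with -0.09 in KO clone 1 and -1.01 in KO clone 5. It passed as lower with KO clone 1 left out (edgeR adjusted p = 0.0159). The list's median was 0.26 in KO clone 1 and 0.22 in KO clone 5.

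Of 15 members of the RNA-sensing list 6 rose and 0 fell by edgeR (7 and 2 adjusted over the list alone), and as a group they did not pass camera (median 0.13, camera adjusted p = 0.104) but passed fry upward (fry adjusted p = 0.00025). DDX58, which encodes RIG-I, rose from 7.77 ± 1.2 to 11.7 ± 0.8 CPM (0.60, SE 0.12, edgeR adjusted p = 0.0028) and IFIH1, which encodes MDA5, from 1.12 ± 0.26 to 2.36 ± 0.47 CPM (1.05, SE 0.21, edgeR adjusted p = 0.0041). Both are also on the interferon-stimulated list, as are DHX58, OAS1, OAS2 and OAS3, so these lists are not independent. IFIH1 lost its call with clones summed (0.0704) and without KO clone 5 (0.0760), the highest of its alternatives, which began at 0.00077.

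Among 23 components of the cGAS-STING pathway, 5 rose and 2 fell (6 and 3 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.591, direction up, median 0.05, mean -0.15). CGAS, the DNA sensor, rose from 17.5 ± 3.3 to 23.9 ± 3.1 CPM (0.46, SE 0.13, edgeR adjusted p = 0.024), by 0.63 in KO clone 1 and 0.33 in KO clone 5. STING (TMEM173) was low, at 1.11 ± 0.39 CPM in WT and 0.825 ± 0.27 CPM in KO libraries (-0.38, SE 0.29, edgeR adjusted p = 0.41). IFI16, a nuclear DNA sensor, fell by 4.34 (SE 1.04, 5.29 ± 6.1 to 0.278 ± 0.28 CPM, edgeR adjusted p = 0.010), and SLC19A1, a folate carrier that also imports cyclic dinucleotides, by 0.37 (SE 0.07, 87.3 to 67.6 CPM). BANF1, which coats DNA at the nuclear envelope, rose by 0.28 (SE 0.07, 132 to 160 CPM) and the ubiquitin ligase gene TRIM56 by 0.31 (SE 0.08). Of the WT libraries, WT clone 1 replicate 1 held 23.25 CPM of CGAS, against 15.1 to 16.64 in the others. The CGAS call was lost in 9 alternatives. Among them were those without WT clone 1 replicate 2 (0.0522) or replicate 3 (0.0585), WT clone 7 replicate 1 (0.0527), KO clone 1 replicate 1 (0.0811) or replicate 2 (0.0776). Replicate number as a block was another (0.43, edgeR adjusted p = 0.0647). Over all alternatives the adjusted p of CGAS ran from 0.00084 to 0.291. IFI16 already differed between the WT clones (-3.30 in clone 7 against clone 1, edgeR adjusted p = 0.045). Its KO value was -3.42 without WT clone 1 replicate 1 and -5.01 without KO clone 5 replicate 2. Its own p ran from 0.00068 to 0.137, and its call was lost in 5 alternatives. IFNB1 and CXCL10 were not analysed here.

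**Figure D1:**
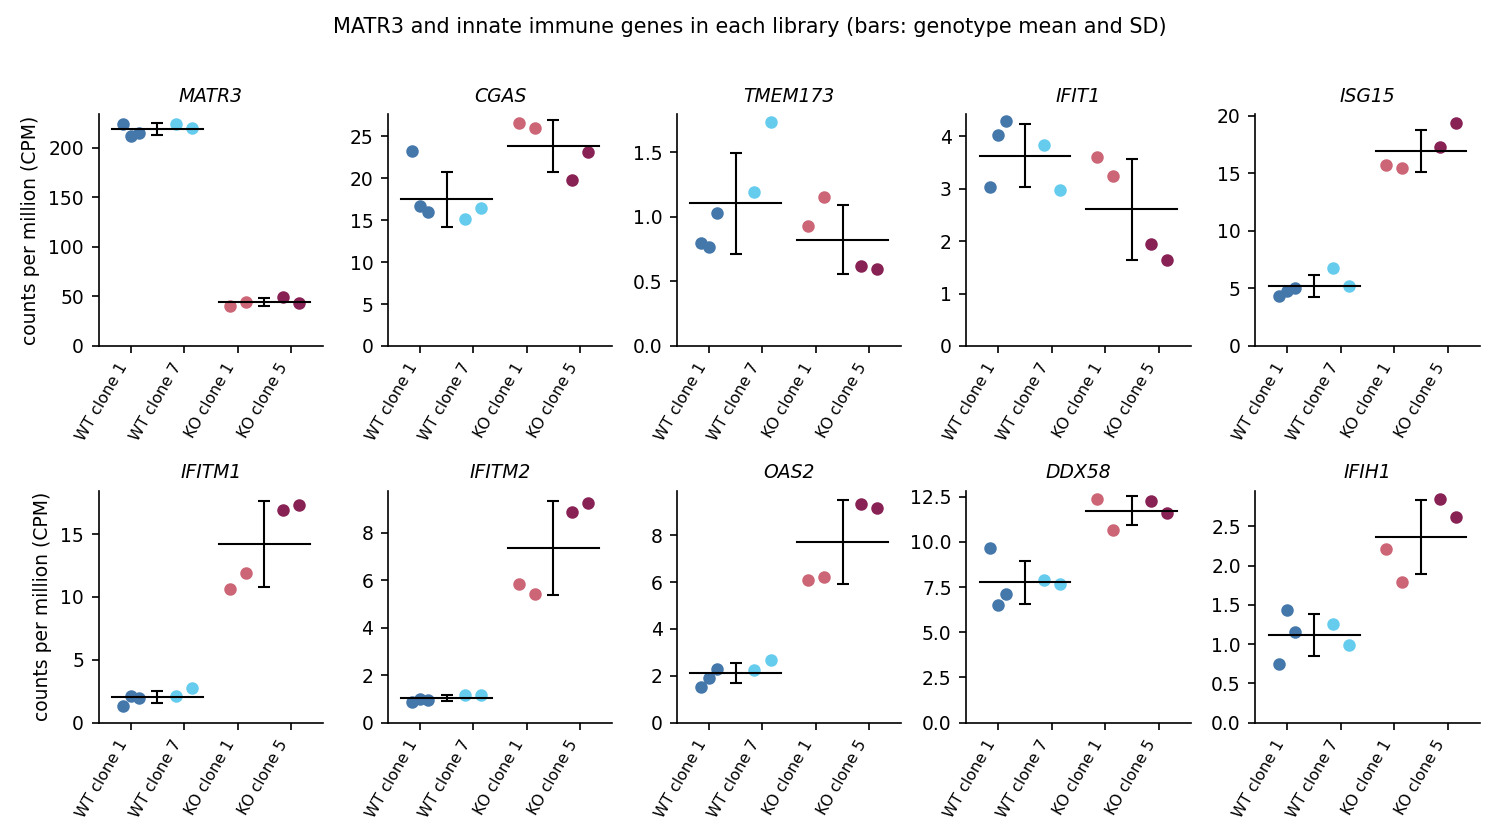
CPM of MATR3 and innate immune genes in each library, with bars at the genotype mean and SD. WT has 5 libraries and KO has 4.

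NF-kB targets gave 3 rises and 1 fall among 17 (the same adjusted over the list alone, median 0.08, camera adjusted p = 0.113). SOD2, the mitochondrial superoxide dismutase, rose from 75.3 ± 3.6 to 128 ± 5.0 CPM (0.76, SE 0.05, edgeR adjusted p = 1.4e-06). The A20 gene TNFAIP3 rose by 1.04 (SE 0.17, 2.80 to 5.82 CPM) and the adhesion molecule ICAM1 by 1.20 (SE 0.25, 1.29 to 2.96 CPM), whereas NFKB1, the p105 subunit, fell by 0.35 (SE 0.07). Of 3 tested interferons and cytokines, too few for camera, 0 passed edgeR over all genes or over the list alone. Antigen presentation by MHC class I was raised, with 5 of 21 members higher and 1 lower (9 and 1 adjusted over the list alone, median 0.18, camera adjusted p = 0.0238, and 0.835 with an estimated correlation). The peptide transporter gene TAP1 rose from 31.3 ± 2.3 to 44.9 ± 2.5 CPM (0.52, SE 0.07, edgeR adjusted p = 0.00015) and HLA-E by 0.38 (SE 0.07, 23.1 to 30.1 CPM). PSMB9, an immunoproteasome subunit gene next to TAP1 whose reads are uncertain for that reason, rose by 1.18 (SE 0.20), and the chaperone gene PDIA3 fell by 0.27 (SE 0.05). The list's call was lost without KO clone 5 replicate 2 (camera adjusted p = 0.0744) and without KO clone 5 (0.134), in a range from 0.00069 to 0.835.

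Epithelial markers rose: 6 of 11 higher and 0 lower by edgeR (6 and 1 adjusted over the list alone, median 0.57, camera adjusted p = 0.0077, and 0.453 with an estimated correlation). Keratin 8 (KRT8) went from 11.2 ± 3.4 to 64.8 ± 5.3 CPM (2.52, SE 0.19, edgeR adjusted p = 1.7e-06) and E-cadherin (CDH1) from 0.0593 to 1.24 CPM (4.41, SE 0.58). The membrane serine protease gene PRSS8 rose by 2.59 (SE 0.36) and the tight junction gene TJP3 from 1.04 to 4.07 CPM (1.94, SE 0.30). The list's call was also lost with the strict filter (camera adjusted p = 0.0655), in a range from 0.00073 to 0.453. CDH1 was at 5.05 without WT clone 1 replicate 2.

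Extracellular matrix genes fell, 9 of 17 lower and 2 higher (10 and 3 adjusted over the list alone, median -0.81, camera adjusted p = 0.0013, and 0.453 with an estimated correlation). The laminin chain gene LAMB1 fell from 76.6 ± 7.7 to 10.4 ± 0.93 CPM (-2.88, SE 0.10, edgeR adjusted p = 5.1e-09). The thrombospondin genes fell too, THBS1 from 7.92 ± 2.7 to 0.437 ± 0.35 CPM (-4.15, SE 0.45) and THBS2 from 52.5 ± 7.1 to 5.91 ± 1.7 CPM (-3.16, SE 0.17), and the collagen cross-linking enzyme gene LOX from 12.9 ± 1.8 to 3.65 ± 0.65 CPM (-1.80, SE 0.15). The rises, chosen after their values were seen, were the collagens COL5A2 (1.37, SE 0.18) and COL1A1 (0.88, SE 0.14). Mesenchymal markers split, 8 of 16 lower and 2 higher (9 and 2 adjusted over the list alone, median -0.41, camera adjusted p = 0.0979). N-cadherin (CDH2) fell from 86.1 to 43.3 CPM (-0.99, SE 0.16), while TPM2 and TWIST2, a transcription factor gene, rose, the second by 2.16 (SE 0.38).

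Genes of the integrated stress response fell, 11 of 25 lower and 2 higher (13 and 4 adjusted over the list alone, median -0.18, camera adjusted p = 0.0041, and 0.835 with an estimated correlation). The cystine transporter gene SLC7A11 went from 61.4 ± 5.8 to 40.5 ± 3.6 CPM (-0.60, SE 0.08, edgeR adjusted p = 0.00025) and ATF3, a stress-induced transcription factor gene, from 12.2 to 8.63 CPM (-0.49, SE 0.08). The amino acid transporter gene SLC7A5 fell from 511 to 404 CPM (-0.34, SE 0.06) and asparagine synthetase (ASNS) from 90.1 to 70.7 CPM (-0.35, SE 0.07). Factors that silence repeats fell as well, 8 of 27 lower and 1 higher (the same adjusted over the list alone, median -0.12, camera adjusted p = 0.0165, and 0.284 with an estimated correlation). APOBEC3C, a cytidine deaminase gene, dropped from 15.9 ± 3.9 to 0.802 ± 0.58 CPM (-4.22, SE 0.37, edgeR adjusted p = 6.6e-06). ATF7IP, the partner of the methyltransferase SETDB1, fell from 90.6 ± 4.3 to 58.0 ± 3.2 CPM (-0.64, SE 0.06) and the helicase gene MOV10 from 124 ± 14 to 85.4 ± 6.6 CPM (-0.54, SE 0.09). HELLS, a chromatin remodeller gene, fell by 0.59 (SE 0.11, 123 to 81.7 CPM).

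Of 397 zinc finger genes 90 fell and 21 rose (98 and 24 adjusted over the list alone, median -0.09, camera adjusted p = 0.0077, and 0.835 with an estimated correlation). ZNF736 fell from 21.8 ± 4.7 to 7.42 ± 0.4 CPM (-1.54, SE 0.14), ZNF251 from 21 ± 1.3 to 9.65 ± 0.37 CPM (-1.12, SE 0.08) and ZNF331 from 31.7 to 19.6 CPM (-0.69, SE 0.07), and ZNF608 rose from 11.8 to 26.3 CPM (1.15, SE 0.07). Cytosolic ribosomal protein genes were slightly raised as a group, 5 of 77 higher and 0 lower by edgeR (1 and 0 adjusted over the list alone, median 0.09, camera adjusted p = 0.0041, and 0.976 with an estimated correlation). RPS12 rose most (1.09, SE 0.07, 392 ± 25 to 832 ± 49 CPM). The list's median was also 0.09 between WT clone 7 and WT clone 1. Their share of all counts was 4.10 ± 0.214% in WT (n = 5) and 4.42 ± 0.186% in KO (n = 4) libraries (exact permutation p = 0.0556). The list's call was lost without WT clone 1 (camera adjusted p = 0.353) or KO clone 1 (0.0721) and with fry (0.172), from 9.1e-06 upward. The 13 mitochondrially encoded genes were lower as a group (median -0.36, camera adjusted p = 0.0465, and 0.976 with an estimated correlation), with a median of -0.43 between WT clone 7 and WT clone 1. By edgeR 1 of them fell past the threshold over all genes and 0 rose, and 0 passed adjusted over the list alone. The mitochondrial share was 2.48 ± 0.60% in WT (n = 5) and 1.90 ± 0.390% in KO (n = 4) libraries (exact permutation p = 0.143). That list passed neither without WT clone 1 replicate 2 (0.116) or replicate 3 (0.103), nor without KO clone 1 replicate 1 (0.137) or KO clone 5 replicate 1 (0.0998) or replicate 2 (0.0669). Its call was also lost with the strict filter (0.0654), a random clone effect (0.0677), the four-group contrast (0.0544) and fry (0.336), and without WT clone 1 (0.140) or KO clone 5 (0.148), in a range from 0.0020 to 0.976.

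In all, 9 of 41 lists passed camera, 4 up and 5 down, and 0 did with an estimated correlation by camera, where 3 had an unadjusted p below 0.05. With fry, which tests a list against no change and not against other genes, 13 passed. These were 7 of the 9, all but the ribosomal and mitochondrially encoded lists, and RNA sensing (fry adjusted p = 0.00025), pluripotency (0.0089), p53 targets (0.0113) and NF-kB targets (0.0218), all up, with haematopoietic markers (0.0176) and chromatin architecture (0.0240), both down. Without WT clone 7 replicate 2 camera with the preset correlation passed 14 lists, and it passed 19 without WT clone 1, 20 without WT clone 7 and 16 without KO clone 5.

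**Figure D2:**
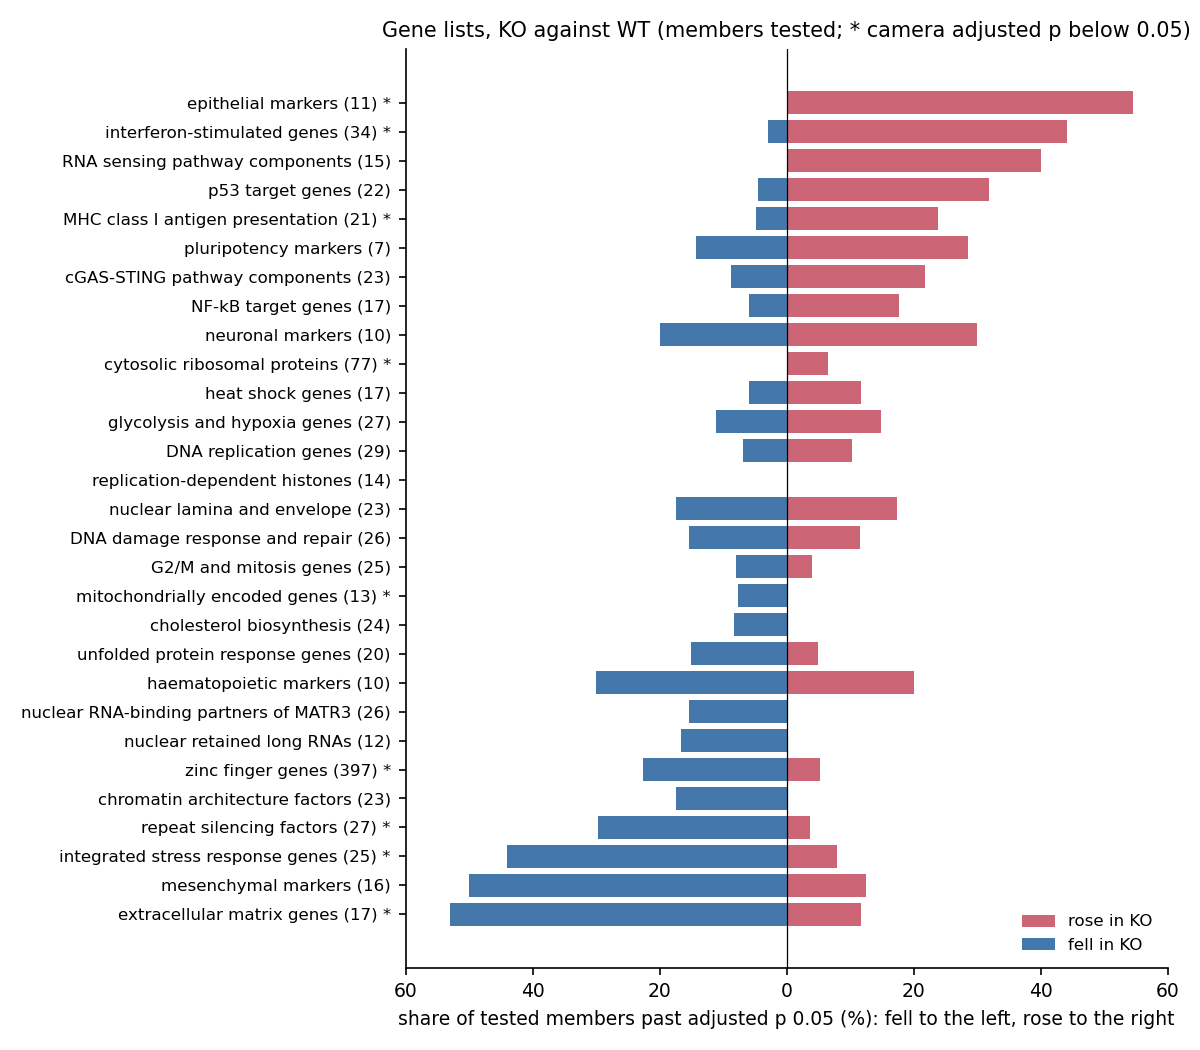
Share of tested members that rose or fell between KO and WT in 29 gene lists. Stars mark lists with a camera adjusted p below 0.05.

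The lists that follow did not pass camera. Of 22 p53 targets 7 rose and 1 fell (9 and 3 adjusted over the list alone, camera adjusted p = 0.123). The cell cycle inhibitor gene CDKN1A rose from 2.87 ± 0.5 to 6.45 ± 1.3 CPM (1.16, SE 0.18, edgeR adjusted p = 0.00053), the repair gene DDB2 by 0.61 (SE 0.06, 21.6 to 33.0 CPM), the antiproliferative gene BTG2 by 0.57 (SE 0.08) and the sestrin gene SESN1 by 0.86 (SE 0.09). The member that fell, named after its value was seen, was MDM2, the p53 ubiquitin ligase (-0.33, SE 0.06). DNA repair genes gave 3 rises and 4 falls of 26 (the same adjusted over the list alone, camera adjusted p = 0.752), among them the checkpoint kinase gene CHEK2 (0.35, SE 0.07) and PRKDC, the DNA-dependent kinase (-0.29, SE 0.07, 841 to 688 CPM). Mitosis genes gave 1 rise, BUB1 (0.52, SE 0.07, 134 to 192 CPM), and 2 falls of 25 (1 and 1 adjusted over the list alone, camera adjusted p = 0.894), CENPF the deeper (-0.42, SE 0.07, 518 to 388 CPM). In replication 3 rose and 2 fell of 29 (the same adjusted over the list alone, camera adjusted p = 0.468), with MCM5 at 0.27 (SE 0.07) and RRM2 at -0.36 (SE 0.08).

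Nuclear partners of MATR3 gave 4 falls and 0 rises of 26 by edgeR (2 and 0 adjusted over the list alone, median -0.07, camera adjusted p = 0.0845). Among them were SAFB2, a scaffold attachment factor gene, at -0.35 (SE 0.07, 93.1 to 73.1 CPM) and the helicase gene DHX9 at -0.28 (SE 0.07, 479 to 396 CPM). Chromatin architecture gave 4 falls and 0 rises of 23 (the same adjusted over the list alone, median -0.06, camera adjusted p = 0.0506), with the cohesin factor gene PDS5B at -0.44 (SE 0.06, 90.7 to 66.7 CPM) and SATB1 at -0.33 (SE 0.06). Of 23 lamina and envelope genes 4 rose and 4 fell (4 and 5 adjusted over the list alone, median -0.01, mean 0.02, camera adjusted p = 0.857), with the nesprin gene SYNE1 at 0.96 (SE 0.10, 11.9 to 23.2 CPM) and the lamin B receptor (LBR) at -0.38 (SE 0.09, 190 to 146 CPM). Among nuclear retained RNAs 2 of 12 fell and 0 rose (2 and 1 adjusted over the list alone, camera adjusted p = 0.536), RPPH1, the RNase P RNA, by 0.44 (SE 0.11). The 14 histone genes held 0 edgeR calls over all genes or adjusted over the list alone (camera adjusted p = 0.384).

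Of 20 genes of the unfolded protein response 1 rose, DERL3 (0.75, SE 0.16, 4.61 to 7.77 CPM), and 3 fell (the same adjusted over the list alone, camera adjusted p = 0.312). Of 17 heat shock genes 2 rose and 1 fell (the same adjusted over the list alone, camera adjusted p = 0.239). Cholesterol synthesis gave 2 falls of 24 and 0 rises (the same adjusted over the list alone, camera adjusted p = 0.935, median 0.02 and direction up but mean -0.09). Glycolysis and hypoxia genes gave 4 rises and 3 falls of 27 (6 and 4 adjusted over the list alone, median -0.01, mean 0.06, camera adjusted p = 0.752). The lactate exporter gene SLC16A3 rose by 0.98 (SE 0.15, 47.6 to 94.0 CPM) and enolase 2 (ENO2) by 0.55 (SE 0.09), and the prolyl hydroxylase gene EGLN3 fell by 1.04 (SE 0.17, 21.3 to 10.3 CPM).

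Of 10 haematopoietic markers 2 rose and 3 fell (2 and 4 adjusted over the list alone, median 0.04 but mean -0.61, camera adjusted p = 0.563). The stem cell factor receptor gene KIT fell from 8.48 ± 0.47 to 1.15 ± 0.52 CPM (-2.92, SE 0.24) and the hyaluronan receptor gene CD44 from 8.63 ± 5.1 to 0.465 ± 0.24 CPM (-4.19, SE 0.46). RUNX1 fell by 0.73 (SE 0.15), and the transcription factor gene MYB rose by 1.40 (SE 0.17, 17.2 to 45.4 CPM). Neuronal markers gave 3 rises and 2 falls of 10 (4 and 3 adjusted over the list alone, camera adjusted p = 0.705 upward, while fry pointed down). Synaptotagmin 1 (SYT1) rose by 2.30 (SE 0.38) and the RNA-binding protein gene ELAVL2 fell from 14.4 ± 0.61 to 5.31 ± 0.3 CPM (-1.45, SE 0.08). Of 7 pluripotency markers 2 rose and 1 fell (the same adjusted over the list alone, median -0.03 and mean -0.57 but direction up, camera adjusted p = 0.324). LIN28A, which blocks let-7 maturation, fell from 39.7 ± 17 to 0.316 ± 0.2 CPM (-7.00, SE 0.61, edgeR adjusted p = 6.3e-06). Its paralog LIN28B rose by 0.84 (SE 0.07, 67.0 to 120 CPM) and UTF1 rose by 1.98 (SE 0.18). Of 3 tested germline genes, too few for camera, DAZL fell by 2.63 (SE 0.24, 11.3 to 1.85 CPM) and PRAME rose by 1.53 (SE 0.15, 3.53 to 10.3 CPM), also when adjusted over the list alone. Among genes given above with modest changes, clones summed or a clone left out ended the calls of BANF1, TRIM56, SLC19A1, NFKB1, ICAM1, PSMB9, PDIA3, CDH2, ATF3, SLC7A5, ASNS, HELLS, CHEK2, PRKDC, MCM5, RRM2, SAFB2, DHX9, LBR, RPPH1, DERL3 and RUNX1.

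A scan along the chromosomes in windows of 10 Mb, made after the data had been examined, found the distal long arm of chromosome 6 raised in KO cells and the long arm of chromosome 1 slightly lower. From GRIK2, which starts near base 100962701, to the last gene at 170584692, 188 genes with a mean CPM of at least 5 had a median log2 difference of 0.89 (interquartile range 0.70 to 1.05), or 1.85-fold, and 179 of them lay above 0. Elsewhere the median of 11550 genes was -0.01, and on the rest of chromosome 6 it was 0.02. Of the 188 genes 171 were called higher and 4 lower. The median was 0.86 in KO clone 1 and 0.91 in KO clone 5, with the same boundary gene, and 0.06 between the WT clones. Among genes named above with a position in GENCODE release 44, RPS12, SESN1, TNFAIP3, MYB, SYNE1, LIN28B and CALHM5 lie in the segment and rose. THBS2 lies in it and fell, and CGAS lies outside it. Genes without such a position were not placed, so this tally may leave out members of the segment. On chromosome 1 the shift was smaller. Of 491 genes from 140 Mb on, 389 lay below 0 (median -0.18, interquartile range -0.32 to -0.04), with 166 called lower and 20 higher, and the median of the rest of the chromosome was 0.00. The median of the long arm was -0.16 in KO clone 1, -0.18 in KO clone 5 and -0.08 between the WT clones. Genes named above were not placed on this arm, and the lists were not retested without it. Modest falls given above, of single genes or of lists, may therefore be part of this shift. By a sign test that takes neighbouring genes as independent, 35 of 286 windows passed (15 higher, 20 lower), 5 of them in the chromosome 6 segment and 9 on the long arm of chromosome 1. The medians of the other 21 were at most 0.24 in size. Without the chromosome 6 segment 3893 genes were called (1794 higher, 2099 lower), and all 9 lists still passed camera. Of these lists only the extracellular matrix and ribosomal protein genes have a member in the segment, 1 each. The outcome for the lists was therefore nearly fixed in advance. Lists that passed only fry were not retested without the segment.

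**Figure D3:**
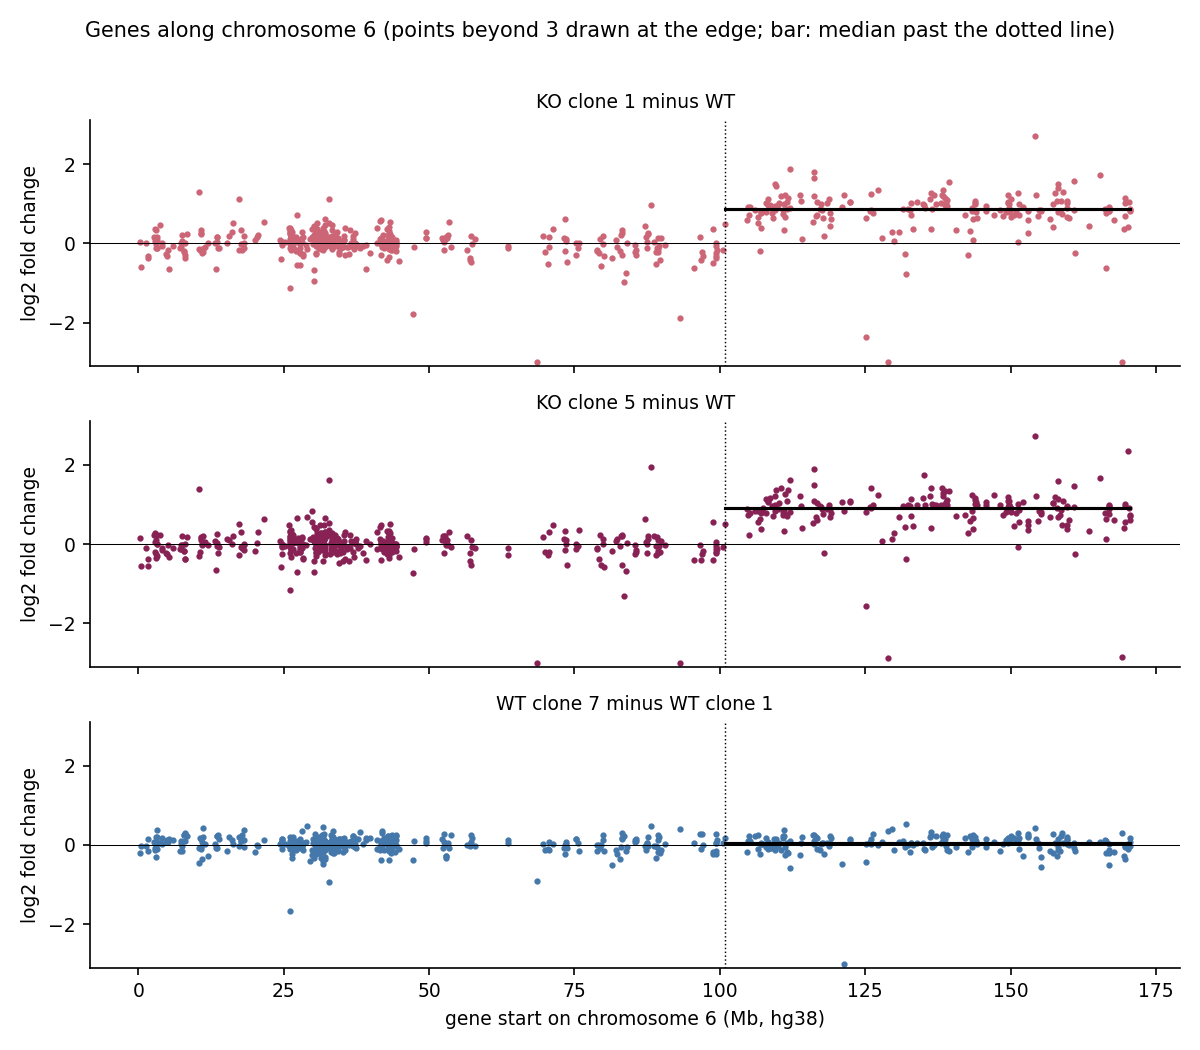
Log2 differences of genes along chromosome 6 for KO clone 1 against WT, KO clone 5 against WT and WT clone 7 against WT clone 1. The dotted line marks the boundary, the bar the median of the segment, and points beyond 3 are drawn at the edge.

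No class of repeats passed as a group, while single subfamilies changed. LTR14C, a long terminal repeat of the ERVK class, rose from 0.449 ± 0.19 to 2.79 ± 0.77 CPM (2.59, SE 0.29, edgeR adjusted p = 4.9e-05), the endogenous retrovirus HERVE_a-int from 3.34 ± 1.2 to 10.5 ± 0.89 CPM (1.67, SE 0.20), and HERV15-int from 2.04 to 4.37 CPM (1.09, SE 0.19). MER61A rose from 10.4 ± 2.1 to 20.8 ± 3.2 CPM (1.00, SE 0.15), MER61-int from 75.9 ± 15 to 144 ± 19 CPM (0.92, SE 0.13) and LTR5_Hs from 293 ± 36 to 369 ± 14 CPM (0.33, SE 0.08). The L1 subfamily L1P3b rose by 1.74 (SE 0.41, edgeR adjusted p = 0.0093), with 0.94 in KO clone 1 and 2.48 in KO clone 5 and p between 0.00034 and 0.166 over the alternatives. The satellite BSR/Beta fell from 3.31 ± 1.4 to 0.961 ± 0.36 CPM (-1.78, SE 0.34, edgeR adjusted p = 0.0025) and CER by 0.99 (SE 0.19). The centromeric ALR/Alpha fell from 33.0 ± 21 to 12.6 ± 1.3 CPM (-1.38, SE 0.33, edgeR adjusted p = 0.010, range 1.3e-05 to 0.107), as did LTR10G (-1.09, SE 0.16) and LTR39-int (-1.05, SE 0.19). HERV9NC-int was at 53.4 ± 49 CPM in WT and 15.9 ± 2.4 CPM in KO libraries (-1.74, SE 0.52, edgeR adjusted p = 0.032), and the difference was -1.03 without WT clone 1 replicate 1, which held 138 CPM. Its call was lost without KO clone 1 replicate 1 (0.0888) or replicate 2 (0.0825), without KO clone 5 replicate 1 (0.0611) or replicate 2 (0.0706), and with replicate number as a block (-1.64, edgeR adjusted p = 0.0623), in a range from 0.0015 to 0.226. Clones summed or a clone left out also ended the calls of LTR5_Hs, LTR39-int, CER (clones summed only) and ALR/Alpha.

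In total 38 of 1052 repeats passed, 16 higher and 22 lower (9 and 6 adjusted over the list alone), 13 of them by at least 2-fold, and 788 lay below 0 (median -0.10). The repeat share of counts was 10.2 ± 2.40% in WT (n = 5) and 9.99 ± 1.15% in KO (n = 4) libraries (exact permutation p = 0.913). The count was 25 without KO clone 1 replicate 1. Without WT clone 1 replicate 1 the balance turned to 31 higher and 18 lower, and the median of all repeats to 0.04. The balance also turned without WT clone 1 replicate 3 (17 higher, 13 lower), KO clone 1 replicate 1 (15 and 10) or replicate 2 (15 and 11) and KO clone 5 replicate 2 (14 and 12), and with replicate number as a block (17 and 11). Against all WT libraries KO clone 1 had 58 repeats called (16 higher, 42 lower) and KO clone 5 had 53 (41 higher, 12 lower). The count also depended on the WT clone used: KO clone 1 had 279 repeats called against WT clone 1 (270 lower) and 32 against WT clone 7 (24 higher), and KO clone 5 had 47 (32 lower) and 147 (143 higher). By class, with rises and falls over all and camera adjusted p, L1 gave 2 and 1 of 129 (0.215), young L1 0 and 0 of 8 (0.425) and L2 0 and 0 of 7 (0.425). In the same form, Alu gave 1 and 0 of 51 (0.113), MIR 0 and 0 of 5 (0.805), SVA 0 and 0 of 6 (0.944, median 0.01, mean -0.01) and DNA transposons 0 and 2 of 223 (0.123). Adjusted over the list alone, edgeR called 0 in each of these classes. ERVK gave 4 and 0 of 40 (3 and 0 adjusted over the list alone, 0.752 upward with median -0.04), ERV1 7 and 14 of 282 (7 and 6 adjusted over the list alone, 0.383), and ERVL 0 and 1 of 115 (the same adjusted over the list alone, 0.105). For ERVL-MaLR there were 0 and 1 of 78 (0 and 0 adjusted over the list alone, 0.752), and for satellites 1 and 3 of 15 (the same adjusted over the list alone, 0.287). Subfamilies share reads, so neighbours in a class are not independent.

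**Figure D4:**
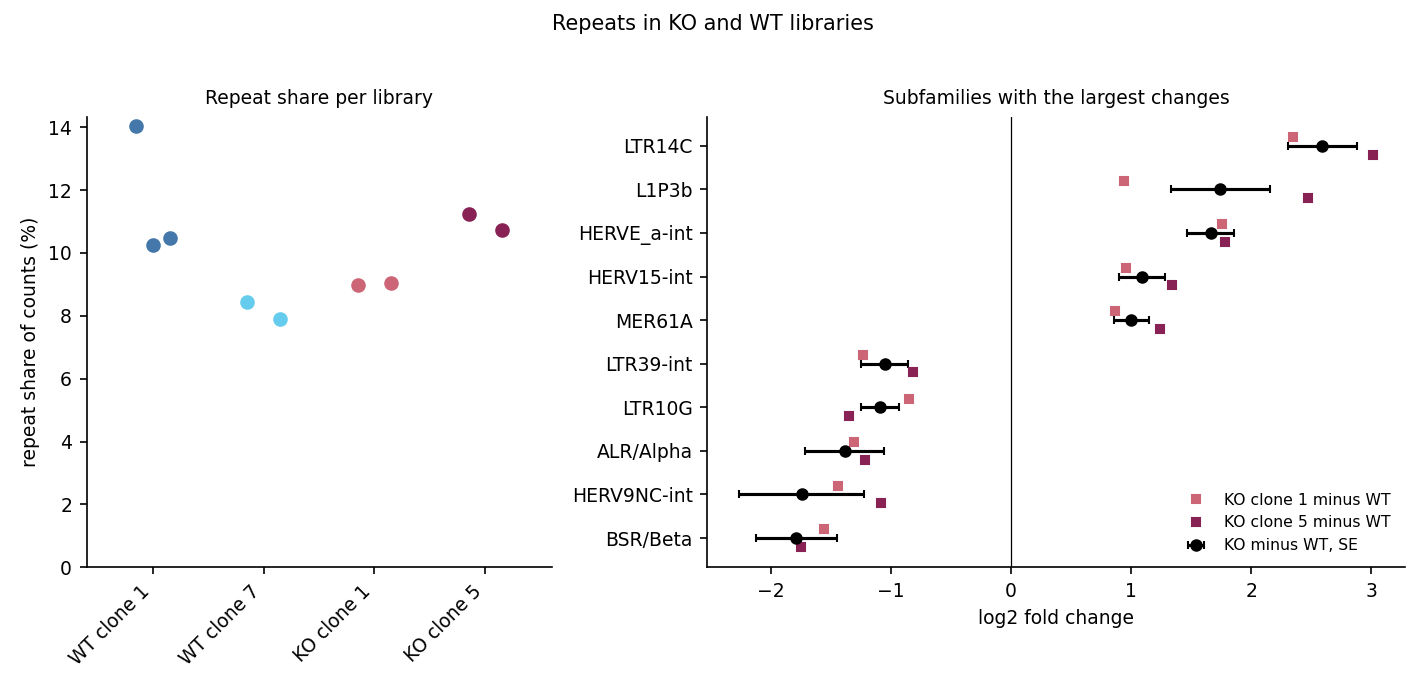
Repeat share of counts in each library, and log2 differences with SE for the repeats with the 5 largest rises and 5 largest falls, with the values of each KO clone.

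Each KO clone changed many of the same genes. KO clone 1 showed the largest rises in NEFL (5.91, SE 0.13), FAT3 (5.4, SE 0.25) and ATCAY (5.18, SE 0.20), and KO clone 5 in FAT3 (6.92, SE 0.23), ATCAY (4.91, SE 0.21) and NEFL (4.64, SE 0.14). Without WT clone 7 replicate 1 the FAT3 values were 6.18 and 7.71. COL11A1 and FUT9 were without counts in each, VEGFC was the third of the deepest falls in KO clone 1, and PPP2R2B, a phosphatase subunit gene, fell from 14.2 ± 3.4 CPM in WT to 0.290 CPM in KO clone 1 and 0 counts in KO clone 5. KO clone 1 differed from WT at 3567 genes (1752 higher, 1815 lower) and KO clone 5 at 3444 (1678 higher, 1766 lower), of which 2441 were shared in the same direction (1180 higher, 1261 lower) and 13 were opposite. The effects correlated at 0.886. Since the clones share controls, simulated unchanged clones gave 0.294 and 0.2 shared genes, and independent lists would share 165 higher and 180 lower. The simulation held no differences between clones and no shared ancestor, so it covers the shared controls only. A shared ancestor of the KO clones could also give shared changes, and these counts cannot tell it from loss of MATR3. Both KO clones carried the chromosome 6 rise with the same boundary gene, GRIK2, which a shared ancestor could give. The KO clones may therefore not be independent replicates of MATR3 loss. With separate controls 1714 genes (correlation 0.754, 40 opposite) or 1734 genes (0.792, 16 opposite) were shared, depending on which WT clone served which KO clone. Against WT clone 1 alone the KO clones differed at 3471 and 2960 genes, and against WT clone 7 alone at 2804 and 3072. Counts fell to 1597 and 1663 for KO clone 1 without its replicate 1 or 2, and to 2021 and 1648 for KO clone 5 without its own. Shared genes came to 1381 and 1411 without KO clone 1 replicate 1 or 2 and 1421 without KO clone 5 replicate 2.

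**Figure D5:**
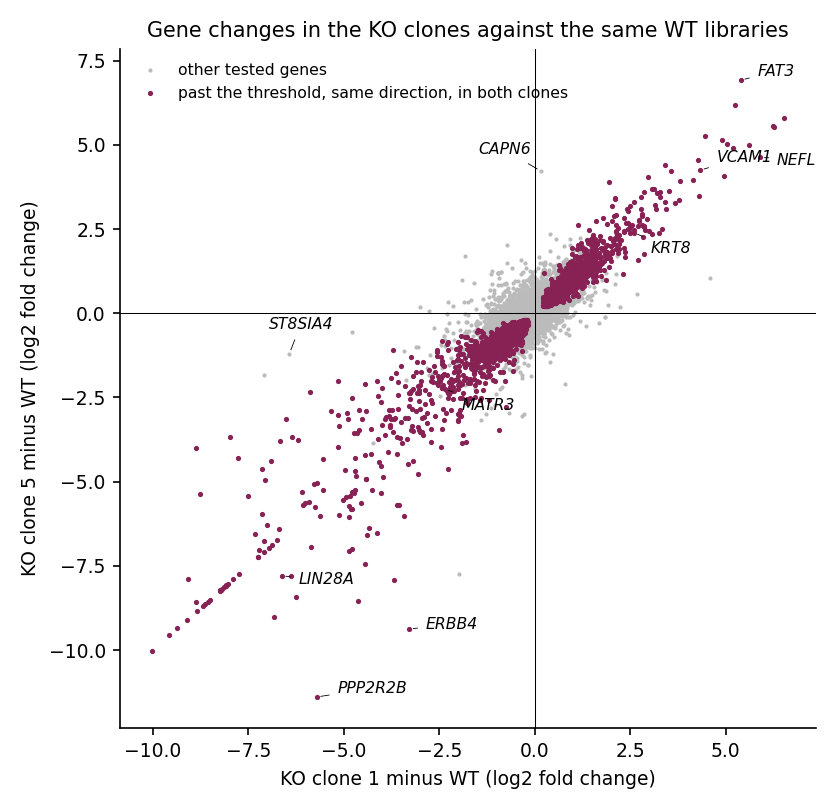
Log2 difference from WT of each gene in KO clone 1 and KO clone 5, with the 2441 genes shared by the clones in colour.

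Clones of a genotype differed at far fewer genes than the genotypes. WT clone 7 and WT clone 1 differed at 109 genes (29 higher, 80 lower in clone 7) and 27 repeats, all lower in clone 7. The interleukin 7 receptor gene IL7R was higher in clone 7 (2.33, SE 0.43, 0.50 to 2.27 CPM, edgeR adjusted p = 0.045), as were KLHDC8A (0.96, SE 0.13, 5.6 to 11 CPM) and GADL1 (0.95, SE 0.14, 4.62 to 8.89 CPM). AMBN, which encodes the enamel protein ameloblastin, was lower (-3.53, SE 0.49, 81.0 to 6.85 CPM), with ZNF208 (-3.87, SE 0.72, 12.8 to 0.918 CPM) and LINC02582 (-3.38, SE 0.46, 8.07 to 0.808 CPM). All of these calls, and all 109, were lost without WT clone 7 replicate 1 or replicate 2, KO clone 1 replicate 1 or replicate 2, or KO clone 5 replicate 1 or replicate 2, where edgeR left 0 genes and 1686 to 2957 had an unadjusted p below 0.05. In that order the adjusted p of the named genes (edgeR) was 0.312, 0.166 to 0.230, 0.0876 to 0.10, 0.0867 to 0.101, 0.0594 to 0.0734 and 0.0650 to 0.0748. Of these genes all but AMBN were also lost without WT clone 1 replicate 3 (0.0529 to 0.0709) and IL7R without WT clone 1 replicate 2 (0.0623). Without WT clone 1 replicate 1 the difference was -2.96 for ZNF208 and -2.82 for AMBN. Without WT clone 1 replicate 3 the count was 3 and without WT clone 1 replicate 1 it was 764. With replicate number as a block it was 431, and DESeq2 called 468.

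KO clone 5 and KO clone 1 differed at 123 genes (83 higher, 40 lower in clone 5). The calpain family gene CAPN6 was higher in clone 5 (4.06, SE 0.44, 0.506 to 9.13 CPM, edgeR adjusted p = 0.0025), with TMEM200A in the chromosome 6 segment (3.53, SE 0.37, 0.926 to 10.7 CPM), and OLFM3, which encodes a secreted olfactomedin, was lower (-2.89, SE 0.35, 4.72 to 0.628 CPM, edgeR adjusted p = 0.0053). These calls were lost without KO clone 1 replicate 1 (0.0741, 0.0605 and 0.0654 in that order) or replicate 2 (0.0719, 0.102 and 0.0772, with CAPN6 at 4.69), and that of OLFM3 also without KO clone 5 replicate 1 (0.0614) or replicate 2 (0.105). The count was 424 without WT clone 1 replicate 1, 79 without WT clone 7 replicate 2, 24 and 18 without KO clone 1 replicate 1 or 2, and 38 and 29 without KO clone 5 replicate 1 or 2.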

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

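No test in this part was chosen after its result was seen. In 7 of 86 groups of WT or KO libraries tested, 1 library lay apart from the rest, where chance gives about 1 in 20, or 4.3. In all 7 it was WT clone 1 replicate 1 against the other 4 WT libraries. Chance alone would spread such cases over libraries of each genotype, so 4.3 is not the number for this library. For CGAS it held 23.25 CPM against 15.1 to 16.64 in the others. For the zinc finger genes ZNF676 and ZNF43 it held 21.96 CPM against 0.5585 to 5.82 and 18.14 CPM against 0.4297 to 4.845. The meiosis gene MEIOB was at 13.32 CPM against 0.3305 to 3.539, and CNTNAP5 at 7.279 CPM against 0.9308 to 2.511. Among repeats HERV9NC-int was at 138 CPM against 18.87 to 47.62 and ALR/Alpha at 70.2 CPM against 21.72 to 25.05. Without this library 32 of the 38 repeats called between KO and WT stayed past the threshold, so it is unlikely to be the whole source of the repeat calls.

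The effects of the KO clones against common controls differed at 123 genes by the test of the difference itself. In KO clone 5 against KO clone 1, CAPN6 was higher by 4.06, TMEM200A by 3.53 and the sialyltransferase gene ST8SIA4 by 5.22, the last resting on 1 count in KO clone 1. The growth factor receptor gene ERBB4 was at -6.09 (0.347 CPM in KO clone 1 and 0 counts in KO clone 5), PPP2R2B at -5.68 (0.290 CPM and 0 counts) and OLFM3 at -2.89. Fitted values at 0 or 1 count depend on the prior count of the model. With replicate number as a block the calls of ERBB4 (-6.07, edgeR adjusted p = 0.0512) and PPP2R2B (-5.65, edgeR adjusted p = 0.0769) were lost. Leaving out single libraries ended these calls too. For ERBB4 the edgeR adjusted p became 0.0683 and 0.0519 without WT clone 1 replicate 2 or 3, 0.0863 and 0.0936 without WT clone 7 replicate 1 or 2, 0.153 and 0.318 without those of KO clone 1 and 0.260 and 0.232 without those of KO clone 5. For PPP2R2B it became 0.0659, 0.0713, 0.0859, 0.0936, 0.194, 0.163, 0.357 and 0.265 in the same order, and 0.0928 with DESeq2. For ST8SIA4 it became 0.0562 and 0.0605 without WT clone 7 replicate 1 or 2, 0.222 and 0.337 without those of KO clone 1 (the fitted value being 7.32 in the latter) and 0.198 and 0.133 without those of KO clone 5.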

How the results depend on the processing

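Of the alternatives, the repeat share in the model and the chromosome 6 segment left out were chosen after seeing the data. MATR3 kept its fall under every alternative, at -2.36 to -2.24, and at -2.35 to -2.26 with 1 library left out. Of 4326 recomputed values for 181 named genes and lists, 3858 kept their direction and side of the threshold, 466 lost the call, 2 gained it (IFIT1, -0.55 with the four-group contrast and -1.03 without KO clone 1) and 0 reversed. Where a filter removed a gene, it has no value there. The settings with most losses were clone sums (66 of 157 values), KO clone 1 left out (53) and KO clone 5 left out (44), which leave fewer samples. Genes called between KO and WT were 4123, with 3206 to 4114 with 1 library left out, 1639 with clone sums, 2338 without KO clone 1, 2614 without KO clone 5 and 1084 at 2-fold. Of the repeats, 38 in all, there were 25 to 49 with 1 library left out, 24 with a random clone effect, 12 with clone sums, 63 with the four-group contrast, 106 without WT clone 1 (98 higher), 117 without WT clone 7 (105 lower), 19 without KO clone 1 and 21 without KO clone 5. With the repeat share of each library in the model 121 were called. Passing lists, 9 in all, were 7 to 14 with 1 library left out, 19 without WT clone 1, 20 without WT clone 7, 16 without KO clone 5 and 0 with an estimated correlation by camera (3 at an unadjusted p below 0.05). Leaving out 1 library gave 1597 to 4527 genes for KO clone 1 against WT, 1648 to 4661 for KO clone 5 against WT, 1381 to 3167 for genes shared by the clones, 0 to 764 between the WT clones (109 with all libraries) and 18 to 424 between the KO clones (123 with all). In such a setting a clone left with 1 library is assumed to vary like the others. Between the WT clones DESeq2 called 468. With libraries paired by replicate number as a block the WT clones differed at 431 genes, and PTBP1 (-0.23, edgeR adjusted p = 0.0513), AHSA1 (0.25, edgeR adjusted p = 0.0733), MLT1F2-int (-0.97, edgeR adjusted p = 0.0825), Charlie12 (-0.64, edgeR adjusted p = 0.0725), MamRep137 (-0.52, edgeR adjusted p = 0.0841) and GSATII (0.25, edgeR adjusted p = 0.0545) lost their calls. Beside these and the losses given with their results, the block changed no other call of a named gene or passing list, while the counts became 3734 genes (3497 of them among the 4123), 28 repeats (26 among the 38) and 11 lists. The cause of the other shifts was not tested.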

Other observations

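Gene families were grouped by symbol and the silent genes listed after the data were seen, and the tests of scaling and of MATR3 loss were chosen only after the chromosome 6 segment was found. Genes named in this part were chosen after their values were seen. Among 383 families, clustered protocadherins, cell surface molecules of neurons, were lower in KO cells, with 15 of 22 falling and 0 rising by edgeR (median -1.21, camera adjusted p = 0.00013, and 0.988 with an estimated correlation). PCDHGC3 fell from 12.9 ± 2.4 to 4.57 ± 0.73 CPM (-1.49, SE 0.15), PCDHGB5 by 1.57 and PCDHGA10 from 7.31 to 3.80 CPM (-0.95). The clusters share exons, so reads of single members are uncertain, and the median was also -0.68 between WT clone 7 and WT clone 1. The other protocadherins had 5 of 8 lower (median -1.09, camera adjusted p = 0.0173, and 0.988 with an estimated correlation). Of 12 GALNT genes, which start O-glycosylation, 8 fell and 0 rose (median -0.56 and -0.09 between the WT clones, camera adjusted p = 0.00013, and 0.988 with an estimated correlation), GALNT13 from 9.97 ± 1.17 to 0.0890 ± 0.062 CPM (-6.91, SE 0.27), GALNT18 by 1.07 (SE 0.11) and GALNT2 by 0.57 (SE 0.07). Of 30 mitochondrial ribosomal proteins of the small subunit 8 fell (median -0.14, camera adjusted p = 0.0286), and so did 4 of 10 ATF genes (median -0.24, camera adjusted p = 0.0280), each at 0.988 with an estimated correlation. Of 8 HOXC entries 4 rose (median 0.59 and -0.37 between the WT clones, camera adjusted p = 0.0286), 1 of them the antisense RNA HOXC13-AS, whose reads are uncertain. HOXC11 rose from 1.39 to 10.3 CPM (2.91, SE 0.17), with reads shared with the antisense HOTAIR uncertain, and HOXC4 by 1.08. These 6 families passed camera, and 0 of the 383 did with an estimated correlation (camera adjusted p = 0.988 for each of the 6, with 14 families at an unadjusted p below 0.05).

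Some genes were silent in every KO library. With at least 1 CPM in all libraries of a genotype and at most 0.1 CPM in all of the other, 21 genes were off in KO and 0 were on. They include FASTKD2, a mitochondrial RNA-binding protein gene (15.9 to 0.0309 CPM), the calcium-binding protein gene S100A6 (11.6 to 0.0264 CPM), the protocadherin gene PCDH17 (6.96 to 0.0498 CPM) and the small GTPase gene RHOB (3.38 to 0.0399 CPM), besides COL11A1, FUT9 and VEGFC. SMN1, the survival motor neuron gene, fell from 27.0 ± 3.4 to 0.851 ± 0.24 CPM (-4.98, SE 0.16, edgeR adjusted p = 5.1e-09), with the caveat that its near-identical paralog SMN2 makes its reads uncertain.

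The chromosome 6 segment was weighed first. An extra copy of the segment, a technical shift of scaling and an effect of MATR3 loss were set against each other. Genes of high and low level shifted alike, the medians of the highest and lowest groups by mean CPM differing by -0.00554, in line with an extra copy. A scaling between libraries would move all genes alike, but the median of genes outside the segment was -0.00632. TMM scaling itself sets most genes near 0, so that value alone does not decide. With library size only, the median was 0.893 in the segment and 0.00196 over all genes. The segment thus moved apart from the other genes, so scaling was excluded. The smaller median of the KO clones was 0.856, in KO clone 1. A rise in each KO clone cannot tell loss of MATR3 from a copy gained once in a shared ancestor. The rise began at the same gene, GRIK2, in each KO clone. It covered 179 of 188 genes, against a median of 0.02 on the rest of chromosome 6. For these genes this argues against an action of MATR3 loss gene by gene. Copy number of the DNA was not measured here.

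For the silent genes, separate drift of each clone and a shared ancestor of the KO clones were compared with loss of MATR3. Clones of a genotype differed at 0 such genes, for the WT and for the KO clones, so separate drift of each clone was excluded. Of 32 genes with such a state in KO clone 1 against WT, 21 had it in KO clone 5, which a shared ancestor that already differed from the WT clones could give as well as loss of MATR3. The data cannot tell these apart.

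For the repeats, the repeat share of the libraries and a single library were weighed against genotype. All 38 stayed called with the repeat share in the model. The share hardly differed between genotypes (10.2% in WT and 9.99% in KO libraries, exact permutation p = 0.913). The fit could therefore hardly have removed calls and does not by itself test the share as a cause. Leaving out WT clone 1 replicate 1 kept 32 of the 38, which excludes that library as the whole cause of the calls. Its part in their balance stays open, since 31 were then higher and 18 lower. The balance also turned without some other single libraries, as given above, so the turn is not particular to that library. With clone as a random effect 24 repeats were called and with clones summed 12, so the number of repeat calls depends on how the spread between clones is counted.

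Among 100 ways to split the 9 libraries into 5 and 4, 1, the real one, called as many genes (4123, highest other 865) and 1 called as many repeats (38, highest other 18). For MATR3, the targeted gene, 1 split gave a difference as large (2.30, highest other 1.50). Only 3 splits keep the clones whole, too few for a share under 0.05. Splits that mix the genotypes carry the genotype difference in their residual spread, and the median of the other splits was 0 genes. For these reasons the splits cannot exclude chance for the genes, the repeats or MATR3. For lists 80 splits passed as many as the 9 found (highest other 27), so chance cannot be excluded for their number. List by list, a comparison chosen after the data were seen, splits with a camera p as small were counted, the real one included. There was 1 for interferon-stimulated genes, the real split itself, 2 for epithelial markers, 5 for repeat silencing and 6 for extracellular matrix. For interferon-stimulated genes the margin was narrow, with an unadjusted camera p of 2.1e-05 in the real split and 2.6e-05 in the closest other. There were 13 for the integrated stress response, 22 for zinc finger genes, 23 for MHC class I, 45 for ribosomal proteins and 52 for mitochondrially encoded genes.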
